A study of Arabidopsis thaliana with 9 samples.

How the data were processed

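Siliques of Arabidopsis thaliana, the seed pods with the seeds inside, were collected 12 days after flowering from 3 kinds of plant, per the labels. Wild type plants were compared with plants that the labels describe as scl15 knockouts without a functional gene and with plants carrying SCL15 behind the promoter of napin, a seed storage protein. SCL15 is a member of the GRAS family of plant transcription regulators. Each kind of plant was represented by 3 libraries, which the labels call biological replicates, so p-values measure the spread between these samples.

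Per the labels' protocols, total RNA was extracted with a column kit and stranded mRNA libraries were prepared for Illumina sequencing. The deposited values are TPM for each gene, a length-corrected share of transcripts scaled to a fixed total, with 1 column per library, per the file headers. Genome build TAIR 10 is named per the submitters' processing notes. The aligner, the counting tool, the use of strand, the annotation version and any filters are not given in the sources used here. The table held 33602 genes, and every library summed to 1000000 TPM over all of them, ribosomal RNA and organelle genes included. A rise of a few very abundant transcripts therefore lowers the TPM of all others. Positions and exon lengths were taken from the TAIR10.1 annotation, in which 97.7% of the genes were found. Gene symbols came from the lists below or else from the deposited gene names, and gene descriptions were the deposited ones. Genes with near-identical copies, such as several LHCB1, LHCB2, RBCS, SESA and HSD1 members, may share reads, and their single values are uncertain. The same holds for overlapping genes.

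TPM keep no depth, so the depth was estimated from low values, which fall on multiples of what 1 read is worth for a gene of given length. Within a tolerance of 5%, 26.7% to 38.7% of low values lay on such multiples, against 10% for a step fixed beforehand. The step was chosen for its fit to these same values, which raises the share found by chance, so this does not test the estimates. The estimates ran from 10.9 to 23.4 M reads (M, 1000000) per library and are approximate. Knockout replicate 3 and overexpression replicate 3 had 65 and 48 genes at 1 estimated read, against 135 to 357 in the others, so both were also left out together.

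Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with an abundance trend in the prior variance. All 9 libraries entered 1 fit, giving 6 residual degrees of freedom, and 3 contrasts were taken from it. Genes with a mean of at least 1 TPM over all libraries were tested, 16555 in all. A gene was called changed at a Benjamini-Hochberg adjusted p of 0.05, and all adjusted p-values of genes are from limma. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes, and errors of fold changes are standard errors (SE). Gene levels are means and SD of TPM over 3 libraries. The SCL15 level was also compared with an exact two-sided permutation test, whose smallest possible p with 3 against 3 libraries is 0.1. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9.

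The lists of genes, the design and most alternatives were fixed before the data were examined. The 17 lists were seed storage proteins, oil body proteins, late embryogenesis abundant (LEA) proteins, seed maturation transcription factors, dormancy and abscisic acid genes, gibberellin genes, SCL15 relatives and chromatin partners, photosynthesis, fatty acid and oil synthesis, heat shock, jasmonate and defence, touch, cold and wounding response, circadian clock, endosperm markers, seed coat and flavonoid genes, silique wall and dehiscence markers, and senescence. They held 287 memberships, of which 33 lay below the level filter. Each list was set against all other genes with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over all 51 list tests. Camera with an estimated correlation and fry, which asks whether a list's genes move, on balance, in a common direction without comparing them with other genes, were alternatives. Beside the calls over all genes, members were also counted with p-values adjusted over the list alone.

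Genes were named by a rule. For each line against wild type it took SCL15 and the 10 rises and 10 falls of largest size among called genes whose groups did not overlap and whose higher group averaged at least 5 TPM, and 5 and 5 for the lines against each other. In each list it took up to 4 called members with the largest change, or up to 2 with the highest level where none was called. List members whose call ended without 1 library were mostly left unnamed, a restriction added after their values were seen. Of the 5 annotated genes on either side of SCL15, those called were named.

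The fold changes of the lines share their wild type libraries, so their relation was set beside simulated unchanged groups sharing those libraries. Neighbouring called genes along the chromosomes were counted against 10000 random draws of as many tested genes. On simulated data with 200 changed genes among 16555, the knockout contrast recovered 11.9% of 1.5-fold, 59.7% of 2-fold and 95.5% of 4-fold changes, with 6 false calls. The overexpression contrast recovered 29.9%, 68.7% and 93.9% of those sizes, with 6 false calls. The contrast between the lines recovered 14.9%, 61.2% and 98.5%, with 9 false calls. No simulated change was called with the wrong sign. No contrast was simulated repeatedly, so differences between these rates may be noise. The data held far more calls than the 200 simulated changes, so the rates do not measure recovery in the data. The neighbour count gave a mean ratio of 0.999 (SD 0.055) over 200 random sets.

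Replicate numbers are shared between the groups in the labels. Deviations of same-numbered overexpression and wild type libraries from their group means correlated at 0.13, 0.18 and 0.15, above the limit of 0.1 set for pairing. For the knockout and wild type the values were -0.06, 0.35 and 0.27, and for the lines against each other 0.07, 0.16 and 0.13, so these did not meet it. The main fit used no pairing in any contrast, that of overexpression and wild type included. Pairing entered only through a replicate block, an alternative that called 5281 genes in the overexpression line against 4149. Of 9 libraries, 8 correlated best, among libraries of the other groups, with one of their own replicate number.

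Alternatives were pseudocounts of 0.1 and 5 TPM, no filter or a mean of 5 TPM, median-ratio scaling over genes of at least 10 TPM, quantile normalization, rescaling without storage protein, oil body and LEA genes, limma without the trend or with robust estimation, only the groups compared, a replicate block, array weights, leaving out each library in turn, a 2-fold minimum and an adjusted p of 0.01. Another 3 were chosen after seeing the data: rescaling without ribosomal RNA, leaving out knockout 3 and overexpression 3 together, and limma voom on the estimated reads. A fit per transcript did not apply, since the values are per gene.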

Results

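Transcript levels were measured in siliques of wild type, scl15 knockout and SCL15 seed overexpression plants, with 3 libraries in each group. The comparisons ask how transcript levels differ from wild type in plants labelled as scl15 knockout and in plants with excess SCL15 in seeds. Between 19679 and 21855 genes were above 0 TPM in a library, and the estimated depth was 10.9 to 23.4 M reads (M, 1000000). Seed storage protein transcripts made up 31.4% ± 1.01 of the total in wild type (SD, n = 3), 32.5% ± 0.478 in the knockout and 42.5% ± 2.62 in the overexpression line. Ribosomal RNA made up 10.04% ± 1.01, 7.20% ± 0.872 and 6.89% ± 2.01 respectively.

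SCL15 itself (AT4G36710) averaged 13.8 ± 2.78 TPM in wild type (SD, n = 3), 5.84 ± 0.886 TPM in the knockout and 550 ± 21.8 TPM in the overexpression line. The knockout thus kept 42.4% of the wild type level, a log2 fold change of -1.10 (SE 0.15, adjusted p = 1.9e-04). Overexpression raised the mean 40.0-fold, a log2 fold change of 5.24 (SE 0.15, adjusted p = 7.0e-11). No library of either line overlapped the wild type range, and the exact permutation p was 0.1 in each comparison, the smallest that 3 against 3 libraries can give. In TAIR10.1 the gene lies on chromosome 4 at 17305758 to 17307648 and is 1 exon of 1891 bases. The labels do not say where in the gene the knockout is disrupted, so it is not known whether the measured exon includes the disrupted part.

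**Figure D1:**
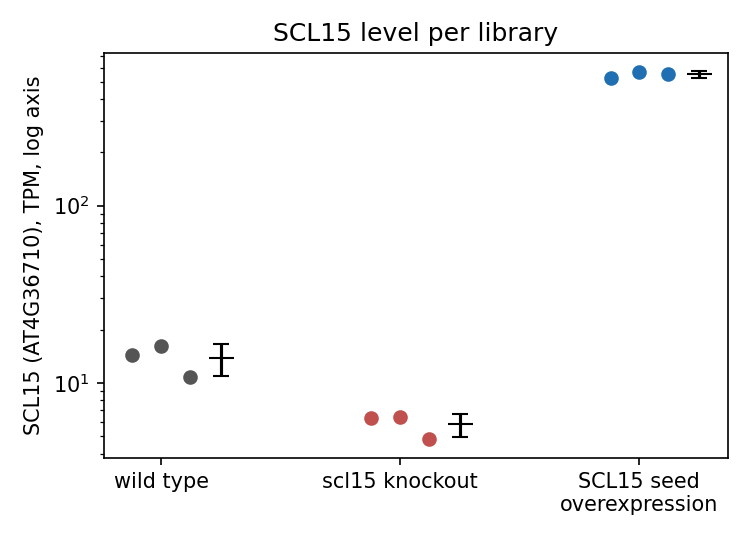
SCL15 level in TPM on a log axis for each of the 9 libraries, as points, with the mean and SD of each group as bars. The knockout libraries lie between 4.82 and 6.39 TPM, the wild type libraries between 10.7 and 16.2 TPM and the overexpression libraries between 526 and 569 TPM.

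In knockout siliques, 21 of 24 transcripts of late embryogenesis abundant (LEA) proteins, which accumulate as seeds acquire desiccation tolerance, fell and 3 were not past the threshold (list adjusted p = 2.7e-32, and adjusted p = 0.0848 with an estimated correlation). EM6 dropped from 402 ± 88.3 TPM in wild type to 17.7 ± 5.89 TPM (SD, n = 3), a log2 fold change of -4.45 (SE 0.20, adjusted p = 2.3e-08). Of 12 heat shock transcripts 7 fell and 1 rose, and the abscisic acid synthesis gene NCED2 fell, while most listed photosynthesis and touch response transcripts rose. In all, 2564 of 16555 genes changed, 1519 higher and 1045 lower, and 848 of these by at least 2-fold (388 higher, 460 lower). The split depended on scaling: with median-ratio scaling, 2403 genes changed, 1167 higher and 1236 lower, and with quantile normalization 2405, 1131 higher and 1274 lower. The median of all genes was 0.10 as deposited and 0.04 with median-ratio scaling. Without wild type replicate 1 the count was 1700, and without knockout replicate 1 it was 1707. The groups did not overlap for 33.0% of genes, against 10% by chance.

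Beside EM6, the falls of largest size in the knockout included 3 more LEA genes, M10 (-4.03), ECP31 (-3.54) and AT4G36600 (-3.54). AT1G24575 fell from 68.3 ± 12.8 to 2.18 ± 0.246 TPM, with a log2 fold change of -4.43 (SE 0.20). The cupin family gene AT5G38940 (-4.21) and CORI3, a coronatine-induced cystine lyase (-3.80), fell. ORS1 (-3.76), AT1G17710 (-3.71) and the carboxylesterase gene CXE17 (-3.57) completed these 10. The 10 rises of largest size came from genes that averaged 2.15 TPM or less in wild type. AT5G51105 rose from 0.980 ± 0.536 to 51.9 ± 21.6 TPM, a log2 fold change of 4.70 (SE 0.30, adjusted p = 3.6e-07). AT2G19802 (4.69), AT1G21395 (4.34), the thaumatin family gene AT1G19320 (3.35), the dirigent protein gene DIR12 (3.27) and AT1G48195 (3.25) followed. AT2G19970 (3.14), AT4G00872 (3.10) and AT5G63230 (3.04) also rose. AT2G02498 was listed at 0 in all wild type and overexpression libraries and averaged 8.75 ± 7.15 TPM in the knockout. All of these 10 rises but DIR12 were highest in knockout replicate 3, so their sizes lean on that library. AT5G51105, for instance, stood at 76.9 TPM there and at 39.2 and 39.7 TPM in the other knockout libraries. All 20 of these rises and falls were also called with median-ratio scaling.

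LEA transcripts had a median log2 fold change of -1.79 in the knockout. Of 24 members, 21 fell, none rose and 3 were not past the threshold, or 23 fell when adjusted over the list alone. The list test gave an adjusted p of 2.7e-32, and adjusted p = 0.0848 with an estimated correlation. Heat shock transcripts had a median of -0.68, with 1 of 12 higher, 7 lower and 4 not past, or 2 higher and 7 lower adjusted over the list alone (adjusted p = 3.2e-06, and adjusted p = 0.0746 with an estimated correlation). HSP17.4 fell from 271 to 31.2 TPM, a log2 fold change of -3.10 (SE 0.24), HSP17.6A had -3.07 (SE 0.24) and HSP17.6C -2.03 (SE 0.35). Among dormancy and abscisic acid genes, 7 of 20 fell, 1 rose and 12 were not past, with equal counts adjusted over the list alone and a median of -0.25. The list was past at adjusted p = 3.1e-04, and adjusted p = 0.246 with an estimated correlation. NCED2, which encodes a 9-cis-epoxycarotenoid dioxygenase of abscisic acid synthesis, fell from 16.1 to 0.684 TPM (log2 fold change -3.37, SE 0.23). AHG1 (-1.73) and ABI1 (-0.70), protein phosphatases that restrain abscisic acid signalling, fell as well. Oil body protein transcripts had a median of -0.23, with 3 of 12 lower, among them the caleosin gene CLO2 (-0.79, SE 0.10), none higher and 9 not past. Counts were equal adjusted over the list alone (adjusted p = 0.0054, and adjusted p = 0.251 with an estimated correlation).

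Photosynthesis transcripts rose in the knockout, with 27 of 28 higher, none lower and 1 not past, or 28 higher adjusted over the list alone, and a median of 0.75. The list was past at adjusted p = 6.7e-17, and adjusted p = 0.249 with an estimated correlation. Examples are the light-harvesting genes LHCB2.3 (1.82, SE 0.25), LHCB1.4 (1.77, SE 0.26) and LHCB1.1 (1.43, SE 0.17) and the Rubisco small subunit gene RBCS2B (1.23, SE 0.19). Touch, cold and wounding response genes had a median of 0.81, with 7 of 9 higher, none lower and 2 not past, and equal counts adjusted over the list alone (adjusted p = 1.3e-05, and adjusted p = 0.249 with an estimated correlation). The zinc finger gene ZAT12 rose by a log2 fold change of 1.37 (SE 0.18) and the xyloglucan endotransglucosylase gene TCH4 by 1.14 (SE 0.12). Circadian clock genes had a median of -0.37, with 2 of 12 higher, 6 lower and 4 not past, or 3 higher and 6 lower adjusted over the list alone (adjusted p = 0.0106, and adjusted p = 0.317 with an estimated correlation). The evening-phased genes ELF4 (-1.58, SE 0.30) and LUX (-0.87, SE 0.13) and the clock output gene GRP7 (-1.24, SE 0.15) fell. Senescence genes had a median of -0.53, with 1 of 7 higher, 3 lower and 3 not past, or 1 higher and 5 lower adjusted over the list alone. The list was past at adjusted p = 0.0152, with adjusted p = 0.249 with an estimated correlation and 0.0583 among genes of at least 5 TPM. The transcription factor gene WRKY53 rose (1.2, SE 0.25), while ORE1 (-0.95, SE 0.17) and the chlorophyll breakdown gene SGR1 (-0.55, SE 0.12) fell.

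The other 9 lists were not past the threshold in the knockout. Seed storage proteins had a median of -0.08 (adjusted p = 0.347): 1 of 13 fell, AT1G03890 (-0.61, SE 0.13), and 12 were not past, also adjusted over the list alone. Seed maturation transcription factors had members in both directions, 4 of 16 higher, 2 lower and 10 not past, or 5 and 2 adjusted over the list alone (median 0.17, adjusted p = 0.783). HSFA9, a seed heat stress factor (-2.30), and ABI5, an abscisic acid response factor (-1.91), fell, while LEC1, a regulator of embryo development (1.49), rose. Jasmonate and defence genes were 6 of 17 higher, 6 lower and 5 not past, or 7 and 6 adjusted over the list alone (median -0.04, adjusted p = 0.297). In that list the vegetative storage protein genes VSP1 (-2.56, SE 0.14) and VSP2 (-1.82, SE 0.16) fell and the defence regulators PAD4 (1.33) and WRKY70 (1.18) rose. Fatty acid and oil synthesis genes were 5 of 21 higher, 2 lower and 14 not past, or 7 and 2 adjusted over the list alone, with a median of 0.33 (adjusted p = 0.318, and 0.0237 without knockout replicate 2). The sucrose synthase gene SUS3 fell (-1.39) and BCCP1, a subunit of acetyl-CoA carboxylase, rose (0.75). Gibberellin genes were 5 of 18 higher, 1 lower and 12 not past, equally adjusted over the list alone (median 0.14, adjusted p = 0.771), the lower one being the receptor gene GID1B (-0.96). Seed coat and flavonoid genes were 3 of 21 higher, 4 lower and 14 not past, equally adjusted over the list alone. Their median was 0.16 but their mean was -0.10 and the list test pointed down (adjusted p = 0.572). The anthocyanin pathway genes LDOX (-1.72) and DFR (-1.62) fell and GL2, an epidermal cell fate regulator, rose (0.82). Silique wall and dehiscence markers were 1 of 10 higher, 2 lower and 7 not past, or 4 and 3 adjusted over the list alone, with SHP1 (-1.33) and ADPG2 (-1.04) lower. Their median was 0.01, their mean -0.06 and the list test pointed down (adjusted p = 0.572). The median became -0.06 with median-ratio scaling. No endosperm marker of 5 was past, on either count (median 0.41, adjusted p = 0.735), with EPR1 at -0.58 (SE 0.25). None of the 9 SCL15 relatives and chromatin partners was past, on either count (median 0.08, or -0.02 with quantile normalization; adjusted p = 0.935), with HDA19 at 0.21 (SE 0.12).

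Of the 10 annotated neighbours of SCL15, all tested, 3 changed in the knockout. HVA22K (AT4G36720), on chromosome 4 at 17307709 to 17309867 in TAIR10.1 and 60 bases from SCL15, fell from 9.24 ± 1.56 to 0.503 ± 0.432 TPM (SD, n = 3), a log2 fold change of -2.80 (SE 0.21, adjusted p = 1.4e-06). PLT6, a polyol transporter gene, rose by 0.93 and GBF1 (AT4G36730), a G-box binding factor gene, by 0.57 on the log2 scale. The rise of GBF1 was not past without wild type replicate 1 (adjusted p = 0.0855), knockout replicate 1 (0.0649) or knockout replicate 3 (0.0741). In the overexpression line HVA22K averaged 6.82 ± 0.762 TPM and was not past the threshold (-0.38, adjusted p = 0.192), and GBF1 was past at -0.55. That call ended with median-ratio scaling (-0.24, adjusted p = 0.346), quantile normalization (-0.26, 0.284) and rescaling without storage protein, oil body and LEA genes (-0.27, 0.313), and without wild type replicate 3 (0.0631) or overexpression replicate 2 (0.0757). AT4G36750 (-0.41, adjusted p = 0.0511) was past there under 9 of 24 alternatives, among them the replicate block (0.0248), without knockout replicate 3 (0.0493) and without overexpression replicate 3 (0.0165), with a range from 0.0089 to 0.8001. AT4G36680 (0.34, adjusted p = 0.139) was past with median-ratio scaling (0.65, 0.0367), quantile normalization (0.0478) and the rescaling (0.0430). AT4G36740 (-0.74, adjusted p = 0.0706) was past there without wild type replicate 2 (0.0441) or overexpression replicate 1 (0.0329). In the knockout AT4G36700 (0.45, adjusted p = 0.102) was past with the replicate block (0.0152) and without knockout replicate 2 (0.0140).

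In overexpression siliques, most LEA transcripts rose and most photosynthesis transcripts fell. AT4G36600, a LEA gene, rose from 28.7 ± 6.06 to 78.5 ± 12.6 TPM (SD, n = 3), a log2 fold change of 1.43 (SE 0.20, adjusted p = 5.5e-04). EM6 rose from 402 ± 88.3 to 856 ± 98.4 TPM, a log2 fold change of 1.104 (SE 0.20, adjusted p = 0.0026). ATSEH, a soluble epoxide hydrolase gene (AT2G26740, chromosome 2 at 11392849 to 11394363 in TAIR10.1), fell from 317 ± 52.1 to 0.214 ± 0.205 TPM, a log2 fold change of -8.04 (SE 0.16, adjusted p = 1.5e-12). Over all genes 4149 changed, 278 higher and 3871 lower, and 478 of them by at least 2-fold (30 higher, 448 lower). This split rested on scaling: with median-ratio scaling 1165 genes changed, 574 higher and 591 lower, with 20.9% of the first calls kept. Quantile normalization gave 543 higher and 577 lower, and rescaling without storage protein, oil body and LEA genes gave 485 higher and 633 lower. The median of all genes was -0.28 as deposited and 0.01 with median-ratio scaling, and list medians are given below beside their difference from it. The count was 2152 without overexpression replicate 2, 2744 without wild type replicate 1 and 2741 without wild type replicate 3. The groups did not overlap for 43.0% of genes, against 10% by chance.

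**Figure D2:**
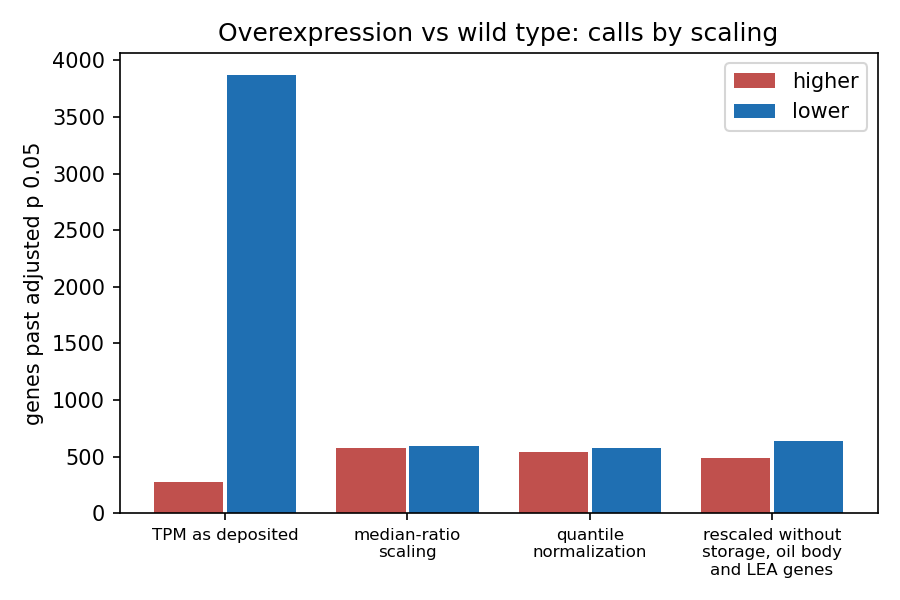
Number of genes past the threshold in the overexpression line against wild type, higher and lower, for TPM as deposited and 3 other scalings. The split of 278 higher and 3871 lower became 574 and 591 with median-ratio scaling, 543 and 577 with quantile normalization, and 485 and 633 after rescaling without storage protein, oil body and LEA genes.

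The rise of largest size in the overexpression line after SCL15 was AT3G01345, from 8.49 ± 2.06 to 85.9 ± 5.92 TPM, a log2 fold change of 3.21 (SE 0.16), with 0.434 ± 0.106 TPM in the knockout. PCR1, named for plant cadmium resistance, rose by 1.28 and was higher in the knockout too (2.64). The LEA genes AT3G53040 (1.19) and AT4G39130 (1.15), the AP2/ERF factor gene RAP2-9 (1.19) and AT5G53260 (1.15) rose, the last not being past with a pseudocount of 0.1 TPM (adjusted p = 0.119). The cutin synthesis gene CYP77A6 (1.14) and the xyloglucan endotransglucosylase gene XTH25 (1.11) rose as well. Among the falls, ESM1 dropped from 33.7 ± 5.19 to 1.16 ± 0.338 TPM, a log2 fold change of -4.01 (SE 0.17), and NSP1 had -2.69 (SE 0.16). Both take part in glucosinolate breakdown. ATDR4 (-3.31), CORI3 (-2.75) and the peroxidase gene PER25 (-2.44) fell in the overexpression line and also in the knockout (-3.24, -3.80 and -2.75). The ribosomal RNA gene AT2G01020 did so too (-2.86 and -2.73). These were mRNA libraries, so its level need not reflect expression of the gene, and it ranged from 2078 to 5216 TPM in wild type. AT4G23670 (-2.50), the nicotianamine synthase gene NAS1 (-2.40) and AT1G02820 (-2.35) completed the 10 falls. In the knockout ESM1 (-1.48), NSP1 (-1.33), AT4G23670 (-0.92) and ATSEH (-0.80) were also called lower, while NAS1 and AT1G02820 were not past. All 20 named rises and falls of the overexpression line were past there with the same sign under median-ratio scaling.

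LEA transcripts rose in the overexpression line, 19 of 24 higher, 1 lower (M17, -0.80) and 4 not past, or 22 and 1 adjusted over the list alone. M17 was not past with median-ratio scaling (-0.47, adjusted p = 0.0738) or quantile normalization (-0.48, 0.0762). The list median was 0.83, or 1.12 above that of all genes (adjusted p = 2.2e-35, and adjusted p = 0.0775 with an estimated correlation). Storage protein transcripts had a median of 0.41, or 0.69 above that of all genes, with 4 of 13 higher, none lower and 9 not past, or 6 higher adjusted over the list alone. The list was past at adjusted p = 7.6e-13, and adjusted p = 0.0746 with an estimated correlation. AT1G03890, a cruciferin-like gene, rose from 2026 to 3235 TPM (0.67, SE 0.13) and the vicilin-like genes PAP85 (0.65, SE 0.14) and AT2G28490 (0.61, SE 0.13) rose likewise, with 1.02, 1.00 and 0.95 for the 3 under median-ratio scaling. Oil body protein transcripts had a median of 0.43, or 0.71 above that of all genes, with 5 of 12 higher, none lower and 7 not past, or 5 higher and 1 lower adjusted over the list alone. Its test gave adjusted p = 1.4e-10, and adjusted p = 0.0746 with an estimated correlation. CLO2 (0.50, SE 0.10) and CLO1 (0.48, SE 0.12), caleosin genes, were among them, with 0.85 and 0.82 scaled. Heat shock transcripts had a median of 0.32, or 0.60 above that of all genes, with 3 of 12 higher, 1 lower and 8 not past, equally adjusted over the list alone (adjusted p = 4.2e-05, and adjusted p = 0.0775 with an estimated correlation). HSP17.4 rose from 271 to 560 TPM (1.08, SE 0.24) and MBF1C, a heat stress coactivator gene, fell (-0.95, SE 0.14, or -0.63 scaled). Under median-ratio scaling these 4 lists kept positive medians of 1.18, 0.75, 0.77 and 0.65.

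Photosynthesis transcripts fell in the overexpression line, with 27 of 28 lower, none higher and 1 not past, equally adjusted over the list alone. Their median was -0.87, a difference of -0.59 from that of all genes (adjusted p = 2.5e-14, and adjusted p = 0.251 with an estimated correlation). With median-ratio scaling 14 members were lower and none higher. In these libraries silique wall and dehiscence markers had a mean of -0.51 (SE 0.07 over 10 genes, adjusted p = 0.0011 with fry and 0.0715 with camera). That SE treats genes of the same libraries as independent. Fry does not set the list against other genes, so its value includes the shift of all genes (median -0.28). Storage protein transcripts made up 42.5% of the total against 31.4% in wild type. LHCB2.3 (-1.71, SE 0.25), LHCB2.1 (-1.51, SE 0.16), LHCB1.1 (-1.42, SE 0.17) and RCA, the Rubisco activase gene (-1.31, SE 0.13), were the examples of largest size. Touch, cold and wounding response genes had a median of -0.77, a difference of -0.48 from that of all genes, with 6 of 9 lower, none higher and 3 not past, equally adjusted over the list alone. With median-ratio scaling 2 of the 9 were lower. The list was past at adjusted p = 0.0061, with adjusted p = 0.391 with an estimated correlation and 0.0527 among genes of at least 5 TPM. TCH4 (-1.03, SE 0.12) and the calmodulin-like gene TCH2 (-0.88, SE 0.13, or -0.55 scaled) fell. Seed maturation transcription factors were 3 of 16 higher, 1 lower and 12 not past, or 3 and 3 adjusted over the list alone. Their median was -0.06 and their mean -0.04, but the list test, which is relative to all genes, pointed up (adjusted p = 0.0078, and adjusted p = 0.403 with an estimated correlation), and the median was 0.25 with median-ratio scaling. The call ended without wild type replicate 2 (adjusted p = 0.126), without overexpression replicate 3 (0.0672), without knockout 3 and overexpression 3 together (0.0673) and with no level filter (0.0751). HSFA9 (0.94, SE 0.21), ABI5 (0.81, SE 0.18) and ABI3, a master regulator of seed maturation (0.63, SE 0.13, or 0.97 scaled), rose.

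The remaining 10 lists were not past the threshold in the overexpression line, and for 7 of them the median was negative as deposited but positive with median-ratio scaling. The list test, being relative to all genes, pointed up for those 7 lists and for endosperm markers against negative medians and means, except that it pointed down for senescence genes. Dormancy and abscisic acid genes were 3 of 20 higher, 7 lower and 10 not past, or 3 and 9 adjusted over the list alone (median -0.28, or 0.05 with median-ratio scaling; adjusted p = 0.422). AHG1 (0.86, SE 0.18), RDO5 (0.77, SE 0.18) and DOG1 (0.65, SE 0.16, or 0.99 scaled) rose, the latter pair being genes required for seed dormancy. Lower calls depended on scaling: ABA2 (-0.50), for instance, was not past with median-ratio scaling (-0.17, adjusted p = 0.497). Circadian clock genes were 0 of 12 higher, 3 lower and 9 not past, equally adjusted over the list alone (median -0.08, or 0.25 scaled; adjusted p = 0.318). The lower members were CCA1 (-1.34, SE 0.24), LHY (-1.32, SE 0.21) and PRR9 (-1.20, SE 0.19), all expressed in the morning. Jasmonate and defence genes were 1 of 17 higher, 2 lower and 14 not past, equally adjusted over the list alone, with VSP1 (-1.51) and VSP2 (-1.15) lower. Their median was -0.13, or 0.19 scaled (adjusted p = 0.155, and 0.0033 without wild type replicate 2). Gibberellin genes were 4 of 18 lower, none higher and 14 not past, equally adjusted over the list alone (median -0.16, or 0.13 scaled; adjusted p = 0.560). The 4, among them SLY1 (-0.70) and RGA (-0.58), were not past with median-ratio scaling. Fatty acid and oil synthesis genes were 1 of 21 higher, 6 lower and 14 not past, equally adjusted over the list alone (median -0.31, or 0.03 scaled; adjusted p = 0.811). PDAT1 (-0.70), FATB (-0.55) and KCR1 (-0.43) fell, but none of them was past with median-ratio scaling, where KCR1 stood at -0.09 (adjusted p = 0.761). Seed coat and flavonoid genes were 7 of 21 lower, none higher and 14 not past, equally adjusted over the list alone, with SBT1.7 at -0.52. No member was past with median-ratio scaling (median -0.33, or -0.01 scaled; adjusted p = 0.772). Silique wall and dehiscence markers were 4 of 10 lower, none higher and 6 not past, or 6 lower adjusted over the list alone, with IND (-0.83), FUL (-0.76) and ALC (-0.74) among them. With median-ratio scaling FUL (-0.43, adjusted p = 0.0887) and ALC (-0.41, 0.0548) were not past and IND stood at -0.51 (0.0487), and with quantile normalization none of the 3 was past (0.0979, 0.0512 and 0.0513). The list median was -0.49, or -0.15 scaled (adjusted p = 0.0715), and the test was past with the replicate block (adjusted p = 0.0444), median-ratio scaling (0.0482), quantile normalization (0.0418), no level filter (0.0172) and without wild type replicate 3 (0.0298). Senescence genes were 1 of 7 lower, SAG13 (-0.89), none higher and 6 not past, equally adjusted over the list alone (median -0.28, or 0.06 scaled; adjusted p = 0.811). SAG13 was not past with median-ratio scaling (-0.55, adjusted p = 0.0876) or the rescaling (-0.57, 0.0859). No endosperm marker of 5 was past, on either count (median -0.30, or -0.10 scaled; adjusted p = 0.692), with EPR1 at 0.20 (SE 0.25). None of the 9 SCL15 relatives and chromatin partners was past, on either count (median -0.15, or 0.15 scaled; adjusted p = 0.692), with HDA19 at -0.19 (SE 0.12).

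Between the lines themselves, most LEA transcripts were higher and all listed photosynthesis transcripts lower in the overexpression line than in the knockout. EM6 differed by a log2 fold change of 5.56 (SE 0.20, adjusted p = 1.0e-09), from 17.7 ± 5.89 TPM in the knockout to 856 ± 98.4 TPM (SD, n = 3). AT3G01345 (5.92), AT4G36600 (4.97), AT3G22490 (4.44) and M10 (4.35) were also higher, and SCL15 itself differed by 6.34. ATSEH (-7.23), AT5G51105 (-5.34), AT1G21395 (-4.64), AT1G78520 (-4.52) and AT2G19802 (-4.32) were lower. In all 8146 genes differed, 1019 higher and 7127 lower, and 2292 by at least 2-fold (453 higher, 1839 lower). With median-ratio scaling the count was 4649, 2128 higher and 2521 lower, with quantile normalization 4649, 2207 higher and 2442 lower, and after rescaling without storage protein, oil body and LEA genes 4888, 1686 higher and 3202 lower. The median of all genes was -0.38 as deposited and -0.02 with median-ratio scaling. The groups did not overlap for 56.7% of genes, against 10% by chance.

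Of 24 LEA members, 23 were higher and 1 lower in the overexpression line than in the knockout, also adjusted over the list alone (median 2.56, adjusted p = 8.1e-44, and adjusted p = 0.0746 with an estimated correlation). Heat shock genes were 8 of 12 higher, 3 lower and 1 not past, equally adjusted over the list alone (median 1.00, adjusted p = 2.2e-08, and adjusted p = 0.0746 with an estimated correlation), with HSP17.4 at 4.18 (SE 0.24). Oil body genes were 8 of 12 higher, 1 lower and 3 not past, equally adjusted over the list alone (median 0.73, adjusted p = 9.1e-09, and adjusted p = 0.0746 with an estimated correlation), with CLO2 at 1.29. Storage protein genes were 6 of 13 higher, none lower and 7 not past, equally adjusted over the list alone (median 0.39, adjusted p = 6.7e-07, and adjusted p = 0.136 with an estimated correlation), with AT1G03890 at 1.29 (SE 0.13). That call ended with quantile normalization (adjusted p = 0.105). All 28 photosynthesis genes were lower, also adjusted over the list alone (median -1.70, adjusted p = 1.2e-15, and adjusted p = 0.249 with an estimated correlation), with LHCB2.3 at -3.53 (SE 0.25). All 9 touch, cold and wounding response genes were lower, also adjusted over the list alone (median -1.33, adjusted p = 6.9e-05, and adjusted p = 0.249 with an estimated correlation), with ZAT12 at -2.26 (SE 0.18). The dormancy list was past upward at adjusted p = 0.0019, and adjusted p = 0.249 with an estimated correlation. Of its 20 members 4 were higher, 5 lower and 11 not past, equally adjusted over the list alone, and the median was -0.02, the mean 0.26 and the median with median-ratio scaling 0.38. NCED2 (3.44), AHG1 (2.59), DOG1 (1.22) and RDO5 (1.19) were the higher ones.

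For 3 more lists the call between the lines depended on scaling. Clock genes were 6 of 12 higher, 5 lower and 1 not past, equally adjusted over the list alone, with CCA1 at -2.20 (SE 0.24) and ELF4 at 1.89 (SE 0.30). Their median was 0.33 and their mean -0.01, and the test pointed up (adjusted p = 0.0052, and adjusted p = 0.263 with an estimated correlation), but was not past with median-ratio scaling (adjusted p = 0.0852), quantile normalization (0.122) or rescaling without storage, oil body and LEA genes (0.0536). Jasmonate and defence genes were 6 of 17 higher, 6 lower and 5 not past, equally adjusted over the list alone, with WRKY70 at -1.34 and VSP1 at 1.05. Their median of -0.09 and mean of -0.06 became a median of 0.31 with median-ratio scaling, and the test pointed up (adjusted p = 0.0126, and adjusted p = 0.757 with an estimated correlation). It was not past with median-ratio scaling (adjusted p = 0.0537) or quantile normalization (0.115). Senescence genes were 2 of 7 higher, 2 lower and 3 not past, or 4 and 2 adjusted over the list alone, with WRKY53 at -1.82. The median was 0.27 and the mean -0.10, and the test pointed up (adjusted p = 0.0340, and adjusted p = 0.253 with an estimated correlation). That call ended with median-ratio scaling (adjusted p = 0.0793), and without knockout replicate 1 (0.0728), overexpression replicate 2 (0.0643) or overexpression replicate 3 (0.0613).

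The other 7 lists were not past between the lines. Fatty acid and oil synthesis genes were 3 of 21 higher, 13 lower and 5 not past, or 3 and 15 adjusted over the list alone (median -0.68, or -0.27 with median-ratio scaling; adjusted p = 0.572), with SUS3 at 1.93 and BCCP1 at -1.29. Seed coat and flavonoid genes were 4 of 21 higher, 11 lower and 6 not past, equally adjusted over the list alone, with LDOX at 1.59. Their median was -0.57, but 6 were higher and 2 lower with median-ratio scaling, and the test pointed up (adjusted p = 0.666). Gibberellin genes were 1 of 18 higher, GID1B (0.99), 8 lower and 9 not past, equally adjusted over the list alone (median -0.49, against 5 higher and 4 lower scaled), and the test pointed up (adjusted p = 0.874). Seed maturation transcription factors were 3 of 16 higher, 8 lower and 5 not past, equally adjusted over the list alone, with HSFA9 at 3.24 and LEC1 at -1.99. Their median was -0.40 and the test pointed up (adjusted p = 0.365). Silique wall and dehiscence markers were 2 of 10 higher, 5 lower and 3 not past, equally adjusted over the list alone (median -0.59, adjusted p = 0.962), with IND at -1.39. Endosperm markers were 1 of 5 higher, 2 lower and 2 not past, or 1 and 4 adjusted over the list alone (median -0.70, adjusted p = 0.998), with ALE1 at -1.31. SCL15 relatives and chromatin partners were 3 of 9 lower, none higher and 6 not past, equally adjusted over the list alone. Their median was -0.22, or 0.13 with median-ratio scaling, and the test pointed up (adjusted p = 0.935). HDA19, a histone deacetylase gene, was lower (-0.40), but stood at 0.01 with median-ratio scaling (adjusted p = 0.949).

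Many genes changed in opposite directions in the knockout and the overexpression line. Of 1087 genes changed in both, 830 (76.4%) moved in opposite directions and 257 in the same direction. EM6, HSP17.4 and HSFA9 fell in the knockout and rose with overexpression, while LHCB2.3 and TCH4 rose in the knockout and fell with overexpression. CORI3, ATDR4 and VSP1 fell in both lines. Genes lower in the knockout and higher with overexpression numbered 183, against 17.5 from independent lists, and those higher in the knockout and lower with overexpression 647, against 355. Genes higher in both numbered 9, against 25.5, and lower in both 248, against 244. These counts depended on scaling. With median-ratio scaling 451 of 565 genes changed in both (79.8%) were opposite, 281 lower in the knockout and higher with overexpression against 42.9 from independent lists, and 170 the other way against 41.7. Genes higher in both were then 26 against 40.5, and lower in both 88 against 44.1. Quantile normalization gave 447 of 561 opposite, and rescaling without storage protein, oil body and LEA genes 429 of 532. Across genes, which are not independent replicates, the fold changes correlated at -0.13 (Pearson) and -0.09 (Spearman), against 0.50 and 0.48 simulated for unchanged groups sharing the wild type libraries. The covariance was -0.0233, against a simulated 0.0190, and with median-ratio scaling -0.0289. As deposited 38.6% of genes had the same sign, but the medians of all genes lay on opposite sides of 0 (0.10 and -0.28), while the simulated changes, with 66.7%, were centred at 0. With median-ratio scaling the share was 47.6%, with quantile normalization 47.8% and with the rescaling 47.5%. Without wild type replicate 3 the Pearson correlation was -0.02 and the Spearman correlation turned positive, at 0.04. Without wild type replicate 1 they were -0.08 and -0.04, and without overexpression replicate 2 -0.09 and -0.05. With 3 wild type libraries the controls could not be split into parts of at least 2 each, so part of the overlap in the same direction may come from the shared controls, which act against overlap in opposite directions.

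**Figure D3:**
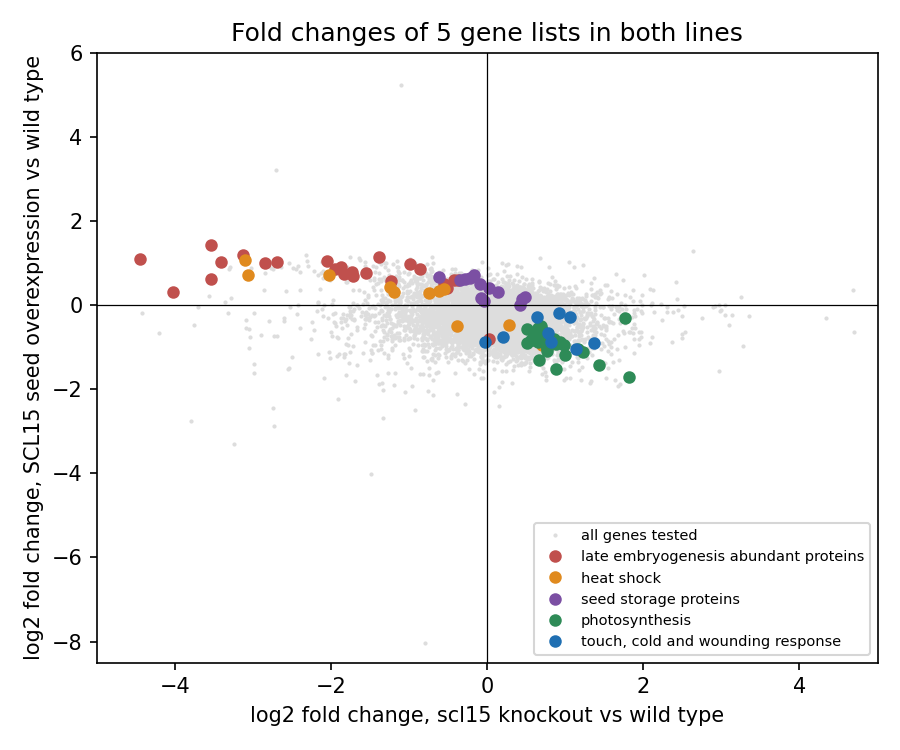
Log2 fold change of each tested gene in the knockout against wild type (horizontal axis) and in the overexpression line against wild type (vertical axis), with the members of 5 lists coloured. LEA members lie mostly at the upper left (medians -1.79 and 0.83) and photosynthesis members at the lower right (medians 0.75 and -0.87), in both cases with the same sign under median-ratio scaling.

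Along the chromosomes, genes called in the knockout lay beside each other more often than in random draws, with 465 neighbouring pairs against 399 expected (ratio 1.16, permutation p = 1.0e-04, the smallest the draws can give). The overexpression line had 1070 pairs against 1015 (ratio 1.05, permutation p = 0.0124), and the contrast between the lines 4086 against 3978 (ratio 1.03, permutation p = 3.0e-04). The draws place calls at random, so neighbours that move together or share reads, such as near-identical copies, can raise these ratios. Their p-values do not measure the spread between samples, and the cause of the excess was not tested. SCL15, HVA22K and GBF1, next to and near each other on chromosome 4, were among the called genes of the knockout.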

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

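Rescaling without ribosomal RNA, leaving out knockout 3 and overexpression 3 together, and voom on estimated reads were tests chosen after the results were seen. Over the alternatives for named genes, 10644 values kept their side of the threshold, 771 were no longer past it, 16 came to be past it and 1 changed sign with a call, while signs of values past in neither were not counted. For the gene lists the counts were 1239, 50, 17 and 8. SCL15 stayed past the threshold with the same sign under each alternative run, from -1.26 to -0.79 in the knockout and from 4.90 to 5.598 with overexpression. The depth behind the values is known only as an estimate, and no alternative could be run on deposited reads. Of simulated 1.5-fold changes 11.9% were recovered in the knockout contrast. That simulation held 200 changed genes, far fewer than were called in the data, so its rate does not carry over to them. Genes not called are not shown to be unchanged.

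With a minimum of 2-fold, 848 genes were called in the knockout, 478 in the overexpression line and 2292 between the lines, and at an adjusted p of 0.01 there were 1389 and 1649 in the first and second of these, all fewer by construction. With an estimated correlation, camera called 0, 0 and 0 of the lists, against 8, 7 and 10 with the preset one. Fry called 11 lists in the overexpression line. By its construction fry does not compare with other genes, and it put 8 lists down there that camera put up. Of these, 4 were past the threshold in either test: seed maturation transcription factors (median -0.058, adjusted p = 0.833), dormancy and abscisic acid (-0.28, 0.0316), gibberellin (-0.16, 0.0134) and endosperm markers (-0.30, 0.0331). The others were SCL15 relatives, fatty acid and oil synthesis, jasmonate and defence, and clock genes. Between the lines it did so for 5 lists, seed maturation transcription factors (-0.40, 0.622), past in neither, and gibberellin (-0.49, 0.0018), SCL15 relatives (-0.22, 0.0234), jasmonate and defence (-0.092, 0.749) and seed coat genes (-0.57, 0.0072).

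Median-ratio scaling called 1165 genes in the overexpression line and 4649 between the lines, quantile normalization 1120 and 4649, and rescaling without storage protein, oil body and LEA genes 1118 and 4888. These scalings moved the median of all genes, from -0.28 to 0.01 in the overexpression line with median-ratio scaling. HDA19 (AT4G38130) changed sign between the lines, to 0.012 with median-ratio scaling (adjusted p = 0.949). Lists past the threshold between the lines were 6 with quantile normalization and 5 with the rescaling, and in the overexpression line 4 with the rescaling, where 3 lists were removed. Ratios of neighbouring calls moved too, and the cause was not tested: with median-ratio scaling to 1.398 (overexpression) and 1.08 (between the lines), with quantile normalization to 1.27 (knockout), 1.399 and 1.08, and with the rescaling to 1.496 and 1.095. With no level filter they were 1.31, 1.23 and 1.07, with a mean of 5 TPM 1.06 (knockout) and 1.01 (between the lines), and without knockout 3 and overexpression 3 together 1.304 (knockout). The correlation of the fold changes was -0.19 with a pseudocount of 5 TPM, -0.080 with no filter and -0.24 with a mean of 5 TPM, and the cause was not tested.

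Leaving out each library in turn gave 1700 (without wild type 1) to 2812 genes in the knockout, with 1707 without knockout 1, and 2152 (without overexpression 2) to 4402 in the overexpression line, with 2744 and 2741 without wild type 1 and 3. Fewer samples were then compared. Neighbour ratios ranged from 1.12 to 1.39, from 1.06 to 1.25 and from 1.01 to 1.04 in the 3 comparisons, and the Pearson correlation from -0.15 to -0.020 (without wild type 3, where the Spearman correlation was 0.043, against -0.12 at its lowest).

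The replicate block called 3442 genes in the knockout, 5281 in the overexpression line and 8863 between the lines. It brought the fatty acid and oil synthesis list (adjusted p = 0.0458) and AT4G36700 (0.0152) past the threshold in the knockout, and the silique wall list (0.0444) and AT4G36750 (0.0248) in the overexpression line, and changed no other call among the named genes and lists. The main fit used no pairing in any contrast. For the knockout against wild type and between the lines, the replicate numbers are only a hint from the data.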

Other observations

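The tests of gene families, of near-absent genes and of every explanation below were chosen after the results were seen, except the overlap of HVA22K with SCL15 and the other splits of the libraries, which were set down before. Other explanations were tried and replaced during the work, among them a harvest stage that varies from sample to sample, another background of the overexpression line, HVA22K falling along with maturation genes, and the chance of such a fall beside SCL15.

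Beyond the fixed lists, 154 families of at least 10 tested genes that share an annotated description were tested with camera. In the knockout 1 was past the threshold, the genes annotated as UDP-glycosyltransferase superfamily. Of its 50 genes 13 fell and 3 rose, with a median of -0.10 against 0.10 for all genes (adjusted p = 0.0059, and adjusted p = 0.981 with an estimated correlation). UGT75C1 (-1.77), an anthocyanin glucosyltransferase, fell from 4.00 to 0.471 TPM, beside falls of UGT90A1 (-1.53), UGT91B1 (-1.39) and UGT72D1 (-0.99). UGT91B1 (1.03) and UGT72D1 (0.98) rose in the overexpression line. There 2 families were past, both pointing up relative to all genes: 73 pentatricopeptide repeat genes (median -0.08, 0 higher and 2 lower) and 10 genes described only as expressed proteins (median 0.10, 2 higher and 1 lower, AT3G01345 alone reaching 3.21), against -0.28 for all genes, each at adjusted p = 0.0059, and 0.981 with an estimated correlation. Most of the pentatricopeptide repeat genes averaged under 10 TPM in wild type, where log2(TPM + 1) understates changes. Their median nearer 0 is therefore not shown to be a response of the family.

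ATSEH was the 1 gene of 7315 with at least 10 TPM in wild type that stood at 5% of its wild type minimum or less in every overexpression library, against 4 such genes in the knockout, AT1G24575, CXE17, AT1G17010 and AT5G55135, the latter pair named after their values were seen. ATSEH was lower in the knockout too, at 181 ± 30.6 TPM (SD, n = 3) against 317 ± 52.1 TPM in wild type (log2 fold change -0.80, adjusted p = 0.0042). Of the 5 annotated genes on either side of ATSEH only 3 were tested, the rest lying below the level filter. Of these 3, 0 were past the threshold in the overexpression line, with SCAB1 at -0.02 (SE 0.18). The cause of the near absence of ATSEH in that line was not tested, so it is not shown to be an effect of SCL15.

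Of the genes called in the overexpression line, 93.3% were lower. Ribosomal RNA took a smaller mean share there, 6.89% ± 2.01 against 10.04% ± 1.01 in wild type (SD, n = 3), which would raise the other genes rather than lower them. That 95.0% were still lower after rescaling without it followed from this difference and is no separate test. After rescaling without storage protein, oil body and LEA genes 56.6% were lower, so the share of the total taken by those transcripts may account for most of the excess of lower calls. That share was 48.7% ± 2.70 against 35.9% ± 1.12 in wild type (SD, n = 3), which alone would shift other genes by -0.32, close to the observed median of -0.28. Whether the abundant transcripts rose or the others fell in absolute amount stays open, since TPM are shares. The share of seed tissue in the overexpression samples was not measured. A difference in that share cannot be told apart from an effect of SCL15 on storage protein, oil body, LEA and photosynthesis transcripts.

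LEA transcripts were lower and photosynthesis transcripts higher in the knockout. Less seed tissue in those samples is argued against by storage protein transcripts, whose mean change was -0.026 (SE 0.091), against -1.95 for LEA members. For the photosynthesis part, harvest at another time of day is a candidate explanation: the morning genes CCA1 and LHY averaged 0.87 and the evening genes ELF4, LUX, GI and TOC1 -0.99, a difference of 1.86 (SE 0.18), or 1.598 (SE 0.16) with PRR9, a morning gene at 0.085 in the knockout and not past. These SE treat genes measured in the same libraries as independent, as does that of the storage protein mean, so they may understate the spread between samples. In the overexpression line the clock difference was -1.55. No library with a recorded hour was compared, so an effect of SCL15 on the clock is equally open and untested. In each genotype, replicate 2 had the highest mean LEA and the lowest mean photosynthesis level. On the log2(TPM + 1) scale these were 7.65 and 8.08 in wild type and 5.80 and 9.01 in the knockout. In the overexpression line they were 8.29 and 7.10. LEA means spanned 0.52 in wild type and 0.65 in the knockout, against -1.95 between these groups. What set libraries of the same genotype apart is not known. A stage or pace of development shared by all knockout samples cannot be told apart from an effect of the knockout genotype, though 76.4% of genes called in both lines moved in opposite directions (79.8% with median-ratio scaling), because no samples matched by stage were compared.

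HVA22K, next to SCL15, was almost lost in the knockout (log2 fold change -2.80). Reads shared with SCL15 are argued against by the annotation, in which the genes overlap by 0 bases. Of 16555 genes 34 fell as far, HVA22K included, and a fall unrelated to position cannot be told apart here, because HVA22K was singled out for its fall. An action of the disruption on the gene beside it may be a hypothesis, since 60 bases separate the genes. It stays open because the disrupted locus was not sequenced in these data. HVA22K stood at 0.503 TPM in the knockout against 9.24 TPM in wild type, while SCL15 kept 42.4% of its level. For the other genes changed in the knockout, effects of lower SCL15 and of lower HVA22K therefore cannot be told apart.

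The 6 libraries of each comparison can be split into equal groups in 10 ways, too few for a share under 0.05. In each of the 3 comparisons 1 split, the real one, gave as many calls, with 2564, 4149 and 8146 genes. The highest of the other splits gave 0. Every other split mixed the genotypes within its groups, so the difference between them entered the spread and low counts were likely beforehand. The 0 is therefore no support for the real split.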
